A study of Mus musculus with 24 samples.

How the data were processed

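The series holds RNA and chromatin measurements from mouse liver, taken at 8.5 months of age from mice labelled C57BL6/CBA. Diethylnitrosamine (DEN) is a liver carcinogen that rodent studies use to bring on hepatocellular carcinoma. The treated mice had received 25 mg/kg of it once, by intraperitoneal injection, per the labels' protocols. The 12 RNA libraries fall into 4 groups of 3: untreated wild type (WT), untreated Smyd3 knockout (KO), DEN-treated wild type (DEN_WT) and DEN-treated knockout (DEN_KO). The labels number a mouse for each RNA library, so the replicates of a group are separate animals as labelled. The knockout is a gene trap in intron 5 of Smyd3, so the exons before it can still be transcribed. Chromatin came from DEN-treated livers and was precipitated with an antiserum against Smyd3 (WT) or an antibody against H3K4me3, the trimethyl mark of active start sites (WT and KO), with 2 replicates of each. The RNA polymerase II precipitations and the input libraries were not analysed here.

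Per the labels' protocols, mRNA was isolated on beads, digested with RNase III, ligated to Ion adaptors and sequenced on an Ion Proton instrument. Per the submitters' processing notes, cutadapt, TopHat2 2.0.9, Cufflinks, Bowtie2 and DESeq were used with mouse build mm9, without a stated role or order. The counting tool, the use of strand, the annotation release and the peak caller are not given in the sources used here. The deposited RNA table holds a score per gene and library, a normalized read count that the authors had divided by 1 factor per library and rounded to whole numbers. This reading rests on the table's own values. Median-ratio factors recomputed from them were 0.999 to 1.00 in every library, and low values skip or repeat at a period that differs between libraries. DEN_KO replicate 1 showed no such period, its estimate being 0.998 reads per unit. Each library's own file held the same value as the series table for all 37583 genes. The GC share of each gene is a fraction that the authors' table gives beside its coordinates, per the file headers. The deposited peak lists give a start and an end for each region and a score of 0 in every line. There is 1 list per group for both replicates, and whether reads were pooled or lists merged is not stated.

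Sums of the values ran from 22320634 to 28973396 per library. The period of the low values put the underlying reads at about 17.0 M (KO replicate 3) to 32.7 M (WT replicate 2), an approximation used only for 1 alternative. Pairs of replicates differed by a chi-square of at least 48.2 per degree of freedom over the genes, so no library looks to be present more than once. Columns of samples outside the series numbered 0. Because the values are scaled and rounded, no counting interval is given for a gene. Mouse-to-mouse spread is given as the SD over 3 libraries.

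The plan, fixed before the data were examined together with the groups, the gene lists, the rule for named genes and the other settings to be tried, had named a quasi-likelihood test on raw counts. The values are not raw counts, so limma 3.58.1 (R 4.3.3) was used on log2(value + 1). Genes with a value of at least 10 in at least 3 libraries were tested, 16471 of 37583. A single fit of the 4 groups left 8 residual degrees of freedom, the spread was moderated with a trend over expression, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The contrasts were DEN_WT against WT, DEN_KO against DEN_WT, KO against WT, DEN_KO against KO, and the interaction, which is the DEN effect in KO minus the DEN effect in WT. Log2 fold changes are on the log2(value + 1) scale, which understates changes of low genes. An exact rank or permutation test of 3 against 3 libraries cannot go below a p of 0.10, so single genes have only the model-based p.

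Gene lists were compared with all other tested genes by limma's camera with a preset correlation of 0.01, adjusted over 35 directional lists. Camera was repeated with a correlation estimated for each list, and fry was run beside it. These lists cover mitosis, DNA replication, liver tumour and oncofetal markers, JAK-STAT and IL6 signalling, growth signalling and proto-oncogenes, EMT and invasion, the acute phase response, pericentral and Wnt target genes, periportal genes, hepatocyte identity, cytochrome P450 and drug metabolism, NRF2 targets, p53 targets, the markers of macrophages, T and NK cells, B and plasma cells, neutrophils, stellate cells and fibrosis, endothelium and cholangiocytes, the interferon response, antigen presentation, ER stress, immediate early genes, heat shock, PPARA targets, lipogenesis, cholesterol synthesis, bile acid synthesis and transport, glycolysis, male-biased and female-biased liver genes, erythroid genes, exocrine pancreas genes and adipocyte genes. Another 4 lists carry no direction: circadian clock genes, SMYD family and H3K4 methylation genes, sex-linked genes and mitochondrially encoded genes. Some lists share members, at most 3 measured genes for a pair (oncofetal and cholangiocyte markers). Members adjusted over the list alone are counted beside those past the threshold over all genes.

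The text names Smyd3, then for each contrast the 8 highest and 8 lowest log2 fold changes among genes past the threshold whose compared groups did not overlap and whose mean level was at least 1 on a log2 per-million scale. Predicted or unnamed genes, pseudogenes and immunoglobulin or T cell receptor segments were left out. Up to 4 members with the smallest p were added for each list described. Genes with near-identical copies (the Mup family, Cyp2a4, Cyp4a10 and Cyp4a14, Gsta2, Acot1, Hspa1a and Hspa1b, and small RNA genes) have uncertain values, since how shared reads were assigned is not stated. The planned choice of 5 Smyd3 peaks by score and the alternatives by peak score could not be made, because every score is 0.

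Peak lists were compared with bedtools 2.31.1 by an overlap of at least 1 bp. Random placements of the Smyd3 peaks on the same chromosomes numbered 100. A gene counted as bound when a Smyd3 peak lay within 1000 bp of its start site in the authors' table, which uses the same mm9 coordinates. The series holds no Smyd3 precipitation from knockout liver, so peaks that do not come from Smyd3 cannot be told apart. Bound genes were compared with other tested genes by camera and by Fisher's exact test, two-sided, where genes are not independent replicates. Confidence intervals of peak shares are 95% Wilson intervals and cover counting error only.

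DEN_WT libraries enter both DEN_WT against WT and DEN_KO against DEN_WT. For the share of genes that moved back in DEN_KO, 50 simulations of unchanged DEN_KO libraries gave an estimate of what the shared libraries alone produce. A change of that share between settings was judged against a jackknife SE of 5.25 points, chosen after its values under the alternatives had been seen. The limma steps were tested on simulated data with gene means from the WT libraries and spread from all 12 libraries, DEN-treated ones included (14959 genes). Known changes were put into the simulated KO group. The test found 4 of 67 genes changed by 1.5-fold, 19 of 67 changed by 2-fold and 46 of 66 changed by 4-fold, with fitted log2 changes at 0.98 to 1.01 of the true ones, and 4 of its 80 calls were unchanged genes. Recovery of 4-fold changes fell short of the pass mark first written into that test, and the mark was then dropped. The alternatives planned ahead were other filters, a replicate block, leaving out each library, a fit of the compared groups only, other set tests and other overlap rules. Other pseudocounts, trimmed mean scaling, quantile normalization, a GC correction with and without the replicate block, and voom weights on approximate reads were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and GenomicRanges 1.54.1 were used beside limma.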

Results

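Livers from 12 mice gave 16471 genes with enough signal to test. Another 21112 genes of the deposited table were left out by the filter, 7930 of them with a value of 0 in every library. Libraries of the same group correlated with r between 0.956 and 0.978. The first principal component held 41.2% of the variance and the second 19.9%. The 10 highest genes made up 27.6% of all values in DEN_WT on average, against 18.1% in WT, 17.0% in KO and 16.6% in DEN_KO, which bears on every share-based scale.

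**Figure D1:**
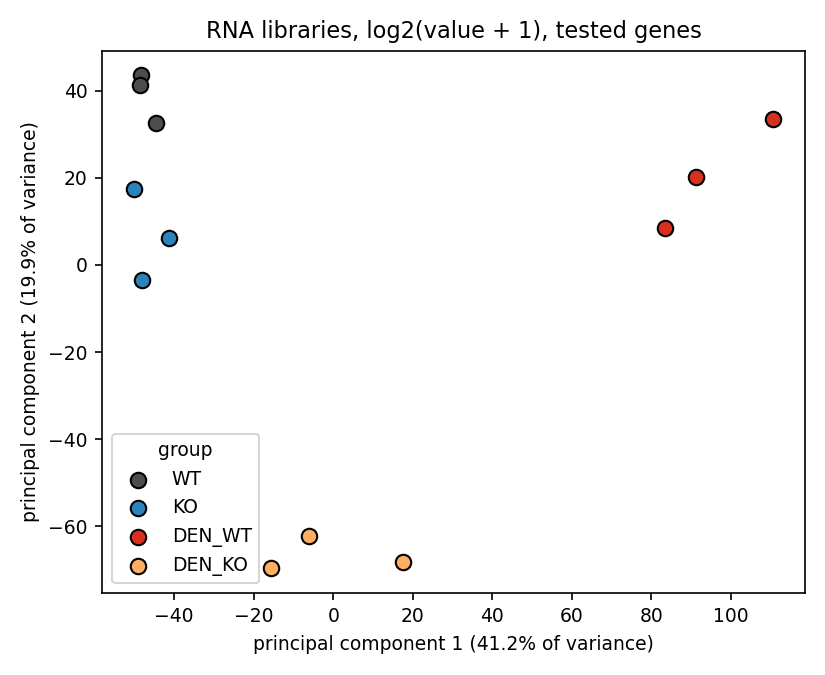
Principal components of the 12 liver libraries on log2(value + 1), with each library drawn as a point coloured by group. The share of variance of each axis is printed beside it.

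Smyd3, the targeted gene, read 79, 89 and 59 in the WT libraries, 29, 17 and 22 in KO, 57, 71 and 74 in DEN_WT, and 12, 3 and 8 in DEN_KO. Group means were 75.7 ± 15.3 (WT), 22.7 ± 6.03 (KO), 67.3 ± 9.07 (DEN_WT) and 7.67 ± 4.51 (DEN_KO; mean ± SD, n = 3 each). In limma it was lower in DEN_KO than in DEN_WT (log2 fold change -3.13 ± 0.41 SE, adjusted p = 0.00018) and fell with DEN in KO livers (-1.58 ± 0.41, adjusted p = 0.022). In KO against WT the difference was -1.71 ± 0.41 with an adjusted p of 0.065, so it was not past the threshold there, and DEN did not move it in WT (-0.15 ± 0.41, adjusted p = 0.81). The call in DEN_KO against KO was lost without KO 1 or DEN_KO 2 (adjusted p = 0.082 each). The values count the whole gene, including exons upstream of the trap.

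DEN raised fetal and tumour-linked liver genes in wild type livers by large factors. Tff3, a mucosal repair peptide, went from 0.667 ± 1.16 to 2344 ± 1203 (n = 3; log2 fold change 10.49 ± 0.87 SE, limma adjusted p = 3.9e-06), and Akr1c18, a steroid reductase, from 1.33 ± 0.577 to 2263 ± 608 (9.91 ± 0.59, adjusted p = 4.2e-07). Afp, the fetal serum protein used as a liver tumour marker, rose from 16.7 ± 9.02 to 3329 ± 1505 (7.61 ± 0.90, adjusted p = 5.8e-05). Gpc3, a cell-surface proteoglycan of hepatocellular carcinoma, rose from 20.7 ± 4.62 to 2771 ± 583 (7.0 ± 0.37, adjusted p = 2.2e-07). Scd2, a desaturase of the fetal liver, rose by 6.14 ± 0.27 (adjusted p = 6.2e-08). The imprinted growth-linked RNA H19 rose by 8.15 ± 1.49 (adjusted p = 0.0013), Tspan8, a tetraspanin of invasive cells, by 7.20 ± 0.61 (adjusted p = 4.4e-06) and the matrix protein Spp1 by 4.15 ± 0.27 (adjusted p = 7e-07). Of 29 oncofetal and tumour markers measured, 23 rose, 0 fell and 6 were not past the threshold (median 3.53, 25 higher when adjusted over the list alone). Camera put the list at an adjusted p of 3.3e-15 with the preset correlation and an adjusted p = 0.1 with an estimated correlation.

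Cell division genes rose together. All 30 mitosis genes were higher with DEN in wild type (median 3.21; 30 adjusted over the list alone, camera adjusted p = 8.1e-15, and adjusted p = 0.2 with an estimated correlation). Cdc20, which activates the anaphase-promoting complex, rose by 4.72 ± 0.63 (limma adjusted p = 0.00015), the cyclin Ccnb2 by 4.46 ± 0.58 (adjusted p = 0.00012). The spindle checkpoint kinase Bub1b rose by 3.49 ± 0.45 (adjusted p = 0.00011) and Cdk1, the kinase that drives mitosis, by 3.24 ± 0.43 (adjusted p = 0.00013). Levels stayed modest and varied between mice, with Cdk1 at 12.3 ± 3.51 in WT and 144 ± 105 in DEN_WT (n = 3). Of 32 DNA replication genes 12 rose, 1 fell and 19 were not past (13 higher and 1 lower over the list alone, adjusted p = 0.0026, and adjusted p = 0.43 with an estimated correlation). In the growth signalling list 7 of 27 rose and 1 fell (median 0.36; 7 higher and 2 lower over the list alone, adjusted p = 0.0051, and adjusted p = 0.1 with an estimated correlation). Its members Myc, a transcription factor that drives growth, and Ccnd1, the cyclin of G1 entry, rose by 2.29 ± 0.33 (adjusted p = 0.00028) and 2.66 ± 0.37 (adjusted p = 0.0002).

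Damage and signalling lists moved the same way in DEN_WT. Of 23 p53 targets 12 rose and 0 fell (median 1.39; 15 higher and 2 lower over the list alone, adjusted p = 1.1e-05, and adjusted p = 0.2 with an estimated correlation). Among them Psrc1, a spindle protein, rose by 6.74 ± 0.55 (limma adjusted p = 3.5e-06) and Btg2, an antiproliferative gene, by 4.03 ± 0.26 (adjusted p = 7e-07), from 191 ± 8.19 to 3157 ± 535. Of 14 immediate early genes 11 rose and 0 fell (median 1.75; 11 over the list alone, adjusted p = 8.8e-05, and adjusted p = 0.1 with an estimated correlation), with Egr1, a growth-factor-induced transcription factor, up by 5.34 ± 0.73 (adjusted p = 0.00017). The JAK-STAT and IL6 list had 7 of 22 members higher and 1 lower (8 and 1 over the list alone, adjusted p = 0.019, and adjusted p = 0.27 with an estimated correlation), among them Lepr, the leptin receptor, at 3.40 ± 0.35 (adjusted p = 2e-05). Of 26 acute phase genes 9 rose and 3 fell (10 and 3 over the list alone, adjusted p = 0.0065, and adjusted p = 0.48 with an estimated correlation). Lcn2, an iron-binding protein of inflamed liver, rose from 54.3 ± 11.6 to 14033 ± 2449 (7.99 ± 0.68, adjusted p = 4.4e-06). Igfbp1, a liver-secreted IGF-binding protein, rose by 8.32 ± 0.81 (adjusted p = 1.3e-05).

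Some matrix, macrophage, interferon and vessel genes rose as well. Col1a1, the main fibrillar collagen, rose by 3.77 ± 0.51 (limma adjusted p = 0.00017) and the matrix protein Sparc by 3.51 ± 0.47 (adjusted p = 0.00014). In all, 12 of 25 stellate and fibrosis genes were higher with 1 lower (median 1.18; 13 and 1 over the list alone, adjusted p = 0.00023, and adjusted p = 0.27 with an estimated correlation). In the EMT and invasion list 9 of 18 rose and 1 fell (9 and 1 over the list alone, adjusted p = 0.00029, and adjusted p = 0.1 with an estimated correlation), with Tgfbr2, a receptor for TGF-beta, at 1.73 ± 0.22 (adjusted p = 0.0001). Gpnmb and Trem2, markers of lipid-laden macrophages, rose by 5.47 ± 0.83 (adjusted p = 0.00037) and 3.43 ± 0.65 (adjusted p = 0.0015). Of 26 macrophage genes 8 were higher and 0 lower (8 over the list alone, adjusted p = 0.0051, and adjusted p = 0.56 with an estimated correlation). Of 26 interferon genes 14 rose (median 0.88; 14 over the list alone, adjusted p = 9e-06, and adjusted p = 0.28 with an estimated correlation). Oas1a, an antiviral synthetase, and Ifit2, an interferon-induced RNA-binding protein, rose by 3.64 ± 0.37 (adjusted p = 1.7e-05) and 2.23 ± 0.32 (adjusted p = 0.00024). Antigen presentation had 8 of 13 members higher (11 over the list alone, adjusted p = 0.00052, and adjusted p = 0.27 with an estimated correlation). Endothelial markers had 11 of 20 higher (12 over the list alone, adjusted p = 0.00032, and adjusted p = 0.1 with an estimated correlation). Cholangiocyte markers had 7 of 12 higher (7 over the list alone, adjusted p = 0.00052, and adjusted p = 0.1 with an estimated correlation).

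Several lists of liver metabolism genes fell, though hepatocyte identity, periportal and lipogenesis genes had no common direction past the threshold. Cyp2b10, an inducible drug-metabolizing enzyme, went from 2301 ± 403 to 128 ± 147 (n = 3; -4.83 ± 0.60 SE, limma adjusted p = 7.8e-05). Cyp2c54 fell by -3.14 ± 0.39 (adjusted p = 7.7e-05) and the carboxylesterase Ces1d by -2.02 ± 0.23 (adjusted p = 4.5e-05). Of 27 P450 and drug metabolism genes 20 fell and 1 rose (median -1.74; 22 and 1 over the list alone, adjusted p = 7.7e-10, and adjusted p = 0.21 with an estimated correlation). Bile acid genes had 17 of 21 lower and 0 higher (median -1.32; 18 over the list alone, adjusted p = 2.2e-07, and adjusted p = 0.21 with an estimated correlation). There the uptake carrier Slco1b2 fell by -2.66 ± 0.34 (adjusted p = 0.00011) and Cyp27a1, a hydroxylase of bile acid synthesis, by -2.18 ± 0.31 (adjusted p = 0.00026). Pericentral and Wnt target genes had 9 of 17 lower and 1 higher (13 and 1 over the list alone, adjusted p = 0.00032, and adjusted p = 0.27 with an estimated correlation). PPARA targets had 15 of 26 lower and 2 higher (median -0.92; 17 and 2 over the list alone, adjusted p = 0.00032, and adjusted p = 0.41 with an estimated correlation), with Acaa1b, a peroxisomal thiolase, at -2.05 ± 0.26 (adjusted p = 0.0001). Heat shock genes had 3 of 11 lower (5 over the list alone, adjusted p = 0.0051, and adjusted p = 0.43 with an estimated correlation). Cholesterol synthesis rose instead, with 11 of 23 higher and 0 lower (13 and 2 over the list alone, adjusted p = 0.00052, and adjusted p = 0.27 with an estimated correlation), led by Sqle, the squalene epoxidase, at 2.15 ± 0.21 (adjusted p = 1.2e-05).

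Sex-biased liver genes moved toward the female side in DEN_WT, although the Y-linked genes were read in all 12 libraries. Of 17 male-biased genes 15 fell (median -2.25; 16 over the list alone, adjusted p = 1.7e-08, and adjusted p = 0.2 with an estimated correlation), among them Hsd3b5, a male steroid dehydrogenase, by -3.16 ± 0.40 (limma adjusted p = 0.00011). Of 18 female-biased genes 10 rose and 3 fell (median 3.19; 11 and 3 over the list alone, adjusted p = 0.00081, and adjusted p = 0.1 with an estimated correlation), among them Cyp2a4, a steroid hydroxylase, from 368 ± 133 to 57940 ± 28747 (7.26 ± 0.48, adjusted p = 8.6e-07). The major urinary protein genes, the pheromone carriers of male mice, fell: Mup11 by -4.42 ± 0.70 (adjusted p = 0.00049), Mup7 by -4.34 ± 0.77 (adjusted p = 0.0011), Mup14 by -4.34 ± 0.61 (adjusted p = 0.00021). Mup18 fell by -4.10 ± 0.69 (adjusted p = 0.00068), Mup17 by -3.93 ± 0.72 (adjusted p = 0.0012) and Mup16 by -3.92 ± 0.73 (adjusted p = 0.0014). Lcn13, a related secreted lipocalin, fell by -3.91 ± 1.07 (adjusted p = 0.014), or by -2.14 without DEN_WT 2. The Mup and Cyp2a copies are near identical, so the value of a single copy is uncertain.

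In all, limma called 4882 genes between DEN_WT and WT (29.6% of tested), 2659 higher and 2223 lower, and 6733 genes had an unadjusted p below 0.05. The higher share of 54.5% became 48.0% with quantile normalization, so which direction is the larger rests on the scaling. Camera put 23 of 35 lists past the threshold, fry 22, and camera with an estimated correlation 0. Swapping libraries between the groups gave 11 to 18 lists past it, and none of the other splits reached 23. Every swapped split still divides the groups unevenly, so it keeps part of the real difference. Such counts therefore do not show how many lists pass by chance alone. Of 54 named genes past the threshold only Eif2s3y was lost when a library was left out (adjusted p = 0.053 without WT 2).

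**Figure D2:**
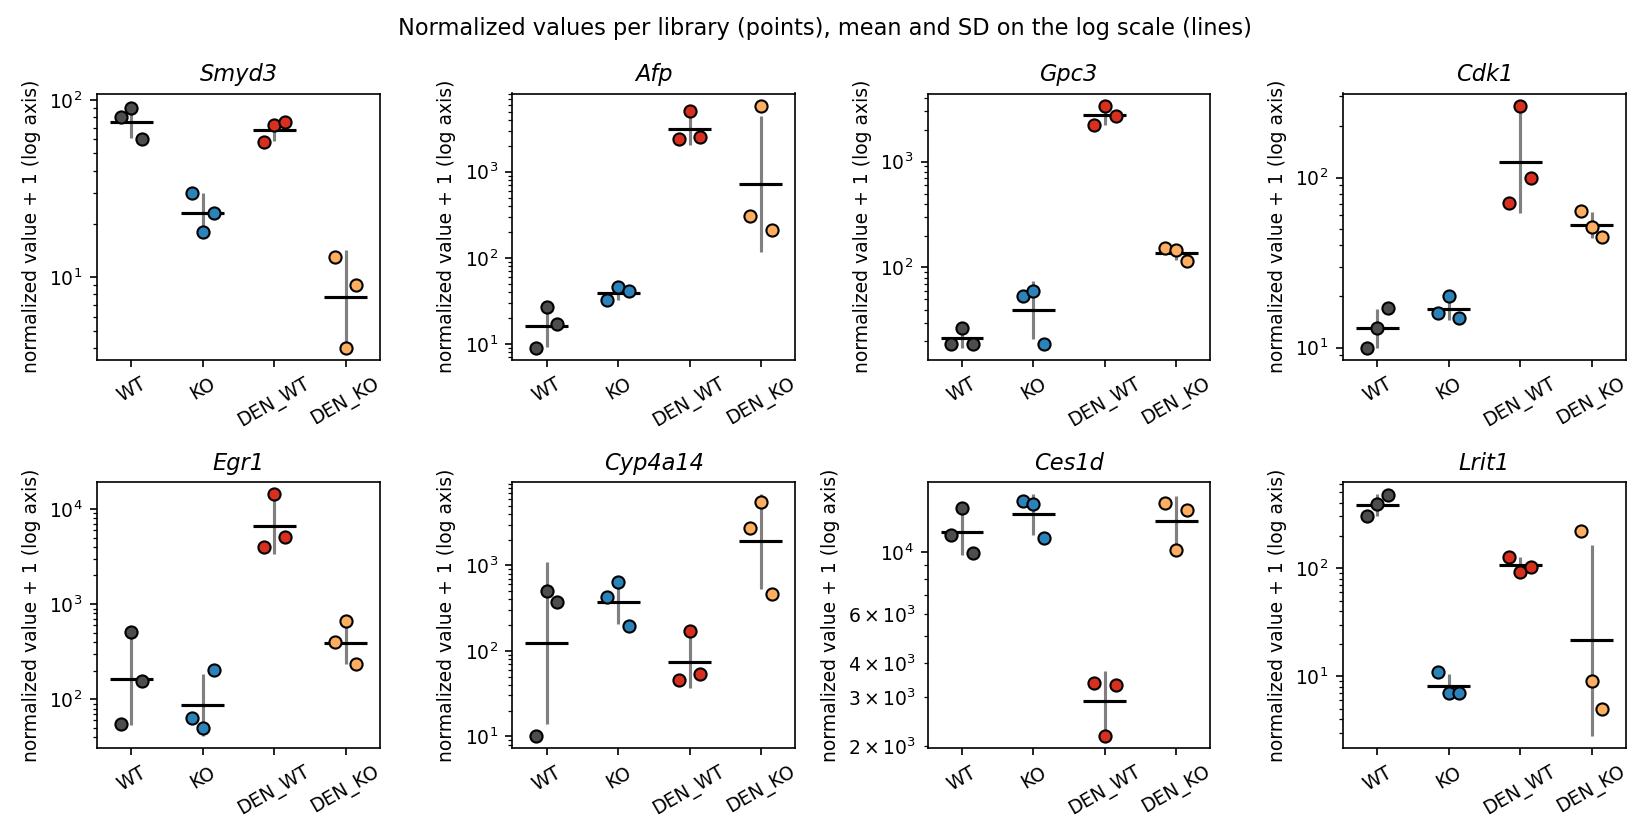
Normalized values plus 1 of Smyd3, Afp, Gpc3, Cdk1, Egr1, Cyp4a14, Ces1d and Lrit1 in each library (points, log axis). Horizontal lines are means and vertical lines SDs on the log scale.

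In DEN-treated knockout livers, many tumour-linked genes were far lower than in DEN-treated wild type. Gpc3 was 137 ± 21.4 in DEN_KO against 2771 ± 583 in DEN_WT (n = 3; log2 fold change -4.32 ± 0.37 SE, limma adjusted p = 2.8e-05). Spp1 was 1164 ± 332 against 13062 ± 3483 (-3.49 ± 0.27, adjusted p = 1.3e-05) and Tspan8 171 ± 115 against 2656 ± 1156 (-4.08 ± 0.61, adjusted p = 0.00038). Akr1c18 was lower by -4.63 ± 0.59 (adjusted p = 0.00016), Scd2 by -2.34 ± 0.27 (adjusted p = 8.8e-05) and Lcn2 by -4.01 ± 0.68 (adjusted p = 0.00082). Cdcp1, a surface protein of migrating cells, was lower by -4.01 ± 0.41 (adjusted p = 4.6e-05). The basement membrane chain Col4a3 was lower by -3.77 ± 0.44 (adjusted p = 9.6e-05) and D17H6S56E-5, a little-studied transcript, by -3.53 ± 0.45 (adjusted p = 0.00016). Of 29 oncofetal markers 16 were lower, 0 higher and 13 not past (median -1.78; 17 over the list alone, camera adjusted p = 4.8e-06, and adjusted p = 0.39 with an estimated correlation). Afp (adjusted p = 0.0866) and H19 (adjusted p = 0.0891) were not past in limma. DEN_KO replicate 2 stood apart, with values of 5867 for Afp against 308 and 208 in the other DEN_KO livers, and 16737 for H19 against 67 and 229. The list's median log2 level was 8.02 there against 6.48 and 6.63.

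Mitosis genes and some matrix genes were lower too. Of 30 mitosis genes 21 were lower and 0 higher (median -1.68; 26 over the list alone, adjusted p = 3.9e-06, and adjusted p = 0.47 with an estimated correlation). Foxm1, the transcription factor of mitotic entry, was lower by -1.64 ± 0.40 (limma adjusted p = 0.0074) and the cyclin Ccna2 by -2.18 ± 0.52 (adjusted p = 0.0066). Without DEN_WT 2 these 2 genes were at -1.14 and -1.58 (limma adjusted p = 0.033 each). Egr1 was lower by -4.07 ± 0.73 (adjusted p = 0.0012). Myc was lower by -1.70 ± 0.33 (adjusted p = 0.0021) and Ccnd1 by -1.60 ± 0.37 (adjusted p = 0.0057). Their lists were not past the threshold. Growth signalling had 8 of 27 lower and 1 higher (camera adjusted p = 0.087) and immediate early genes 5 of 14 lower and 2 higher (camera adjusted p = 0.16). DNA replication had 5 of 32 lower and 2 higher (camera adjusted p = 0.11). Fibrosis genes had 10 of 25 lower and 0 higher (median -1.05; 11 over the list alone, adjusted p = 0.0014, and adjusted p = 0.39 with an estimated correlation), Sparc among them at -3.37 ± 0.47 (adjusted p = 0.00025). EMT genes had 8 of 18 lower and 1 higher (9 and 1 over the list alone, adjusted p = 0.01, and adjusted p = 0.39 with an estimated correlation), with Tgfbr2 at -1.71 ± 0.22 (adjusted p = 0.00017). Of 23 p53 targets 9 were lower and 1 higher (9 and 1 over the list alone, adjusted p = 0.0019, and adjusted p = 0.39 with an estimated correlation), with Btg2 at -2.79 ± 0.26 (adjusted p = 3.6e-05). Cholesterol synthesis had 17 of 23 lower and 1 higher (17 and 1 over the list alone, adjusted p = 0.00011, and adjusted p = 0.39 with an estimated correlation), with Sqle at -1.68 ± 0.21 (adjusted p = 0.00013). Antigen presentation had 6 of 13 lower (6 over the list alone, adjusted p = 0.033, and adjusted p = 0.59 with an estimated correlation). Cholangiocyte markers had 6 of 12 lower (6 over the list alone, adjusted p = 0.015, and adjusted p = 0.39 with an estimated correlation).

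Several lists of metabolic genes were higher in DEN_KO than in DEN_WT, though cholesterol synthesis was lower. Cyp4a14 and Cyp4a10, fatty acid hydroxylases under PPARA, were higher by 4.68 ± 1.23 (limma adjusted p = 0.011) and 4.10 ± 0.95 (adjusted p = 0.0054). Acaa1b was higher by 2.73 ± 0.26 (adjusted p = 3.7e-05) and Acot1, an acyl-CoA thioesterase, by 3.70 ± 0.45 (adjusted p = 0.00012). PPARA targets had 17 of 26 higher and 0 lower (median 0.83; 17 over the list alone, adjusted p = 3.9e-06, and adjusted p = 0.39 with an estimated correlation). The lipid droplet genes Fitm1 and Plin4 were higher by 4.62 ± 0.86 (adjusted p = 0.0015) and 3.85 ± 0.60 (adjusted p = 0.00049). The peptide carrier Slc15a2 was higher by 4.15 ± 1.00 (adjusted p = 0.0066) and the serpin Serpina3c by 4.13 ± 1.08 (adjusted p = 0.01). The small RNA genes Mir5102 and mmu-mir-2134-2 were higher by 4.54 ± 0.81 (adjusted p = 0.0011) and 4.5 ± 0.63 (adjusted p = 0.00025). P450 genes had 21 of 27 higher and 0 lower (median 1.88; 22 and 1 over the list alone, adjusted p = 4e-08, and adjusted p = 0.39 with an estimated correlation), with Ces1d at 2.15 ± 0.23 (adjusted p = 6.3e-05). NRF2 targets had 13 of 25 higher and 1 lower (14 and 1 over the list alone, adjusted p = 8.1e-05, and adjusted p = 0.39 with an estimated correlation). There the glutathione transferases Gsta2 and Gsta4 were higher by 3.13 ± 0.34 (adjusted p = 6.3e-05) and 2.12 ± 0.22 (adjusted p = 5.5e-05). Bile acid genes had 13 of 21 higher (14 over the list alone, adjusted p = 1.2e-05, and adjusted p = 0.39 with an estimated correlation). Male-biased genes had 13 of 17 higher (median 1.59; 14 over the list alone, adjusted p = 9.7e-06, and adjusted p = 0.39 with an estimated correlation). Pericentral genes had 7 of 17 higher and 1 lower (10 and 1 over the list alone, adjusted p = 0.0013, and adjusted p = 0.39 with an estimated correlation). Heat shock genes had 5 of 11 higher (6 over the list alone, adjusted p = 0.033, and adjusted p = 0.59 with an estimated correlation). Adipocyte genes had 3 of 7 higher and 1 lower (3 and 1 over the list alone, adjusted p = 0.041, and adjusted p = 0.52 with an estimated correlation).

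Limma called 5576 genes between DEN_KO and DEN_WT (33.9%), 2708 higher and 2868 lower, with 7363 below an unadjusted p of 0.05. The higher share of 48.6% became 51.9% with trimmed mean scaling, so which direction is larger rests on the scaling. Camera put 16 lists past the threshold, fry 17, and camera with an estimated correlation 0. Other splits of the same 6 libraries gave up to 18 lists, though they too keep part of the real difference. Leaving out a library cost Hspa1a, Hspa1b or Uty its call (highest adjusted p = 0.093) and no other of 47 named genes. Several sets of short genes also had higher medians in DEN_KO. Ribosomal protein genes were at 0.76 against DEN_WT and 0.67 against KO (camera p = 0.15 and 0.13 with an estimated correlation), and other protein-coding genes under 1000 bp at 1.04 and 0.85 (camera p = 0.0057 and 0.0074 likewise). Histone genes were at 1.67 and 1.70 (camera p = 0.064 and 0.024 with an estimated correlation). Small nucleolar RNA genes had lower medians, at -0.36 and -0.26, but no common direction (camera p = 0.96 and 0.35 with an estimated correlation). Against DEN_WT 9 of them were called higher and 4 lower, and against KO 1 higher and 4 lower.

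**Figure D3:**
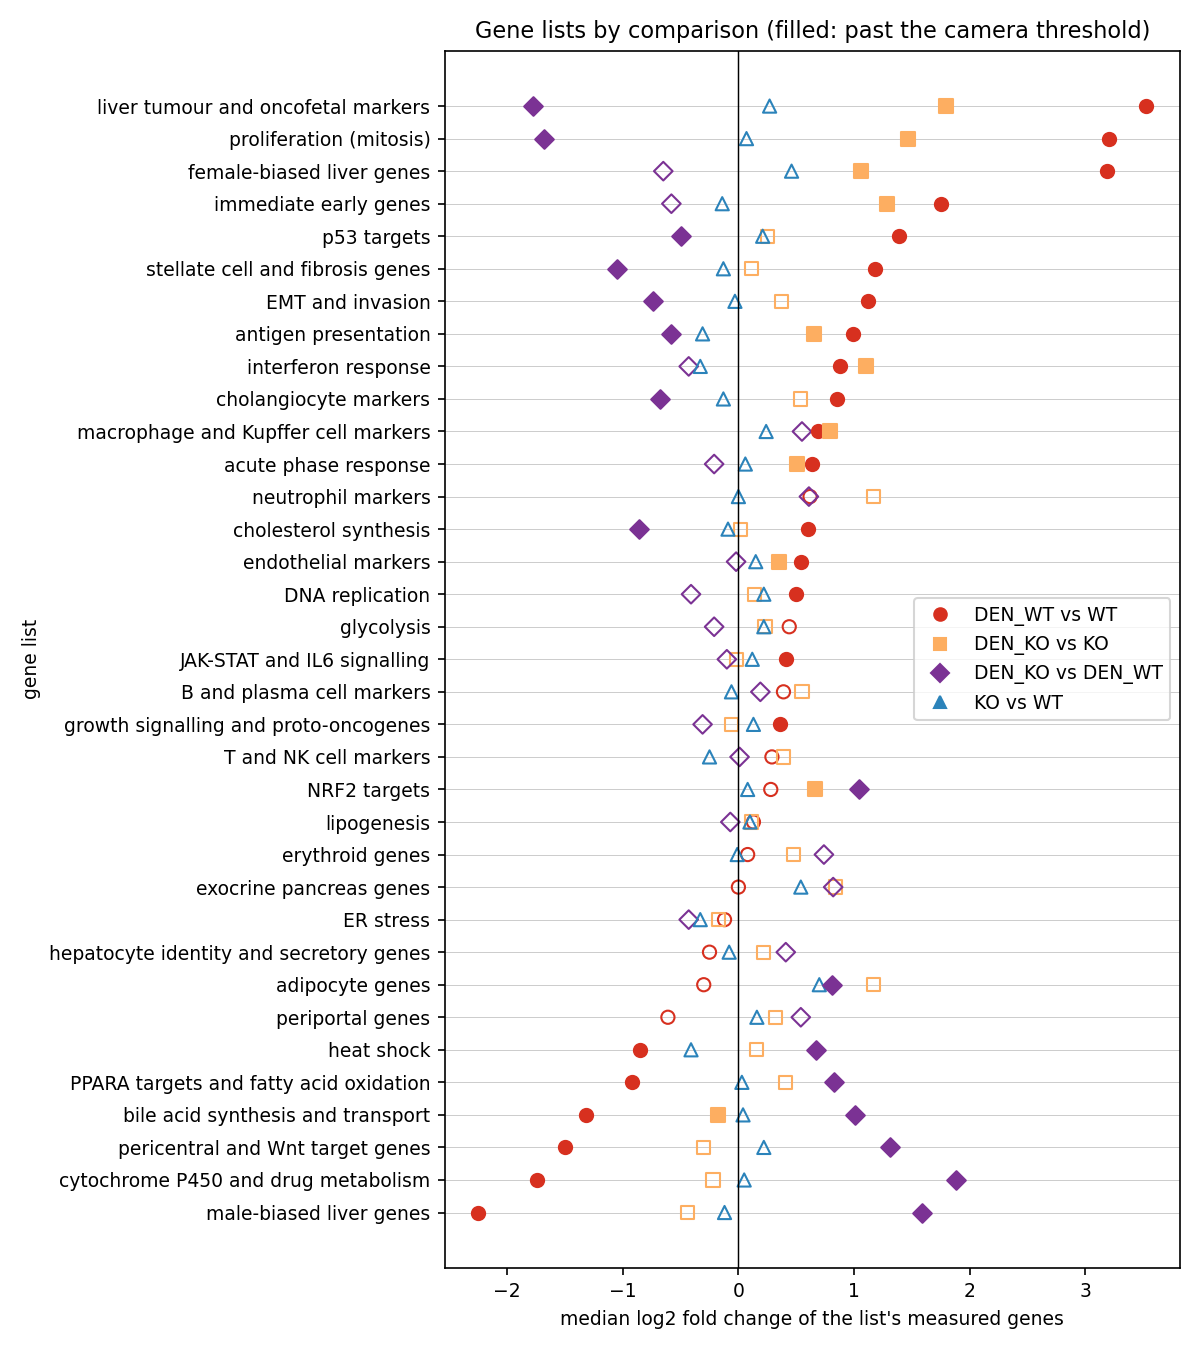
Median log2 fold change of each directional gene list in 4 RNA comparisons, ordered by the DEN effect in wild type. Filled symbols passed camera with the preset correlation, and none passed with an estimated one.

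Most of what DEN had changed in wild type was displaced the other way in DEN_KO. Of the 2659 genes DEN raised, 1482 (55.7%; 463 if the calls were independent, n1 × n2 / N) were called lower in DEN_KO than in DEN_WT, Gpc3, Spp1 and Btg2 among them, and 17 higher. Of the 2223 genes it lowered, 1101 (49.5%; 365.5 if independent) were called higher, Ces1d and Gsta2 among them, and 61 lower. Signs were opposite for 88.1% of the 4882 genes, but the DEN_WT libraries enter both comparisons, and simulated unchanged DEN_KO libraries gave 59.0% (57.7 to 60.2, 50 simulations). The simulations took the observed group means as true, drew noise separately for each gene and called 6118 genes on average. The simulated share and its narrow range may therefore understate what shared libraries alone give. Other splits of the real libraries gave up to 83.4%, though these splits divide the groups unevenly and so keep part of the real difference. The covariance of the 2 fold changes was -0.769 against a simulated -0.071. The counts of 463 and 365.5 under independence take no account of the shared DEN_WT libraries, so they are not a baseline for these calls.

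In knockout livers DEN still raised 15 of 29 oncofetal markers. Tff3 went from 13.3 ± 11 in KO to 3527 ± 3641 in DEN_KO (n = 3; log2 fold change 7.78 ± 0.87 SE, limma adjusted p = 0.00066). Afp rose by 4.21 ± 0.90 (adjusted p = 0.0096), Igfbp1 by 4.21 ± 0.81 (adjusted p = 0.0058), Cyp2a4 by 3.84 ± 0.48 (adjusted p = 0.0008). Tspan8 rose by 3.76 ± 0.61 (adjusted p = 0.0022), Scd2 by 3.70 ± 0.27 (adjusted p = 4.2e-05) and Ly6d, a surface antigen of progenitor cells, by 5.61 ± 0.93 (adjusted p = 0.0026). The DEN_KO 2 liver carried much of the size for Afp and Ly6d, which rose by 2.70 and 4.13 without it (limma adjusted p = 0.0062 and 0.0045). Tff3 was also highest there, at 7636 against 2242 and 703. Mir5102 rose by 4.05 ± 0.81 (adjusted p = 0.0068). The list had 15 members higher and 0 lower (median 1.80; 18 and 1 over the list alone, adjusted p = 8.7e-08, and adjusted p = 0.27 with an estimated correlation). Of 30 mitosis genes 11 rose (median 1.47; 16 over the list alone, adjusted p = 2.8e-07, and adjusted p = 0.74 with an estimated correlation), among them the mitotic kinase Plk1 at 3.04 ± 0.67 (adjusted p = 0.011). Interferon genes rose in 14 of 26 cases with 0 lower (median 1.10; 16 over the list alone, adjusted p = 7e-08, and adjusted p = 0.46 with an estimated correlation). Usp18, a brake on interferon signalling, rose by 2.17 ± 0.39 (adjusted p = 0.0038) and Bst2, which tethers virus particles, by 1.60 ± 0.27 (adjusted p = 0.0028). Immediate early genes had 5 of 14 higher (8 over the list alone, adjusted p = 0.0012, and adjusted p = 0.27 with an estimated correlation), with the orphan receptor Nr4a1 at 5.16 ± 0.60 (adjusted p = 0.00066). NRF2 targets had 6 of 25 higher (8 over the list alone, adjusted p = 0.0011, and adjusted p = 0.27 with an estimated correlation), with the carbonyl reductase Cbr3 at 4.97 ± 0.90 (adjusted p = 0.0041).

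Smaller shifts completed this comparison. Macrophage markers had 4 of 26 higher (4 over the list alone, adjusted p = 0.006, and adjusted p = 0.74 with an estimated correlation). Endothelial markers had 2 of 20 higher (2 over the list alone, adjusted p = 0.0076, and adjusted p = 0.27 with an estimated correlation). Antigen presentation had 3 of 13 higher (5 over the list alone, adjusted p = 0.0096, and adjusted p = 0.74 with an estimated correlation). Acute phase genes had 4 of 26 higher (5 over the list alone, adjusted p = 0.011, and adjusted p = 0.74 with an estimated correlation). Female-biased genes had 3 of 18 higher (5 over the list alone, adjusted p = 0.01, and adjusted p = 0.27 with an estimated correlation). Bile acid genes had 3 of 21 lower (6 over the list alone, adjusted p = 0.043, and adjusted p = 0.77 with an estimated correlation). The homeobox gene Rhox8 fell by -3.93 ± 0.79 (limma adjusted p = 0.0072), the adhesion protein Mdga1 by -2.46 ± 0.39 (adjusted p = 0.0021), the zinc finger gene Zbtb16 by -2.40 ± 0.66 (adjusted p = 0.028). Cyp2b10 fell by -2.26 ± 0.60 (adjusted p = 0.023), the receptor kinase Erbb4 by -1.89 ± 0.56 (adjusted p = 0.039). The nuclear protein Ptma fell by -1.76 ± 0.24 (adjusted p = 0.00086), the phosducin-like Pdcl by -1.65 ± 0.27 (adjusted p = 0.0025) and Ttf1, a terminator of ribosomal RNA transcription, by -1.61 ± 0.37 (adjusted p = 0.013). Leaving out a library cost 9 of 38 named genes their call, Zbtb16, Erbb4 and Cyp2b10 among them (highest limma adjusted p = 0.15), all 9 of them without KO 1 and without DEN_KO 2. Without DEN_KO 2 Erbb4 was at -1.0 (adjusted p = 0.082 in limma), and without KO 3 Ttf1 was at -1.02. Limma called 2460 genes (14.9%; 5001 unadjusted), 1468 higher and 992 lower. The higher share of 59.7% became 69.2% with trimmed mean scaling and 52.8% with quantile normalization, so it rests on the scaling. The count fell to 1170 without DEN_KO 2, 1322 without KO 1, 1353 without DEN_KO 3 and 1610 without KO 2. Camera put 11 lists past the threshold, fry 6, and camera with an estimated correlation 0.

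DEN effects in the 2 genotypes, which share no library, correlated with r = 0.62 over the 4882 genes, with a slope of 0.27 and a smaller size in KO for 92.7% of them. These genes were chosen by passing in wild type, which favours a larger effect there. Over all 16471 tested genes r was 0.39 and the effect was smaller in KO for 57.3%. Shared calls numbered 394 higher (237 if independent) and 280 lower (133.9 if independent), Tff3 and Scd2 among the higher ones.

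**Figure D4:**
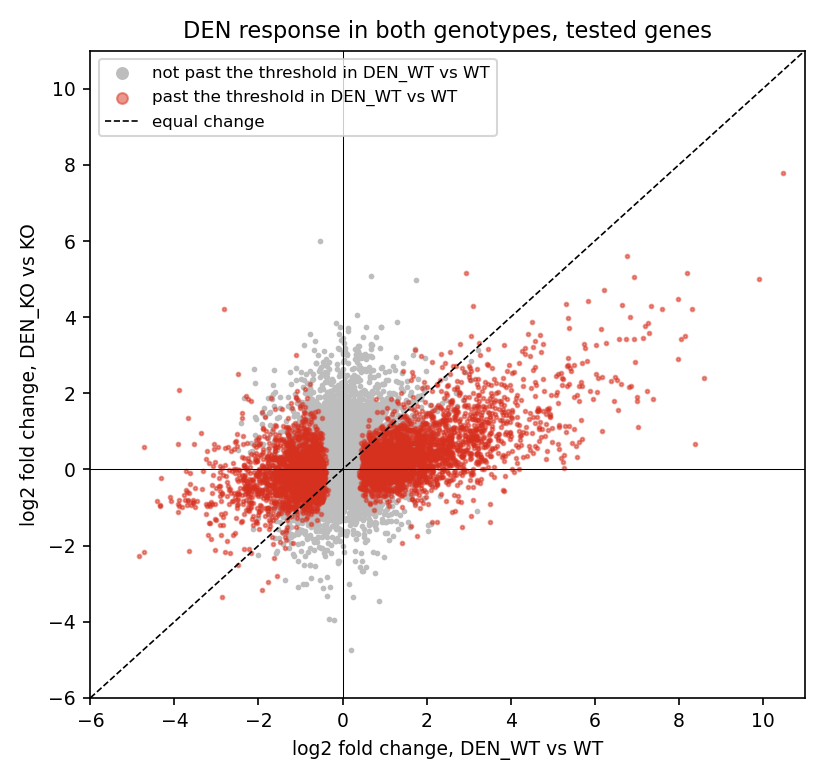
DEN effect in wild type against DEN effect in Smyd3 knockout livers for the tested genes, with those called in wild type in red. The dashed line marks equal change.

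Without DEN, few genes separated knockout from wild type livers. Lrit1, a retinal membrane protein gene, read 390 ± 87 in WT and 7.33 ± 2.31 in KO (n = 3; log2 fold change -5.56 ± 0.97 SE, limma adjusted p = 0.014), and the steroid enzyme Cyp17a1 12.3 ± 12.7 and 469 ± 67.6 (5.55 ± 1.05, adjusted p = 0.024). Also lower were Crym, a thyroid hormone binder (-4.21 ± 0.66, adjusted p = 0.008), the phospholipase Pla2g4b (-3.48 ± 0.37, adjusted p = 0.00058) and Fam25c (-3.40 ± 0.68, adjusted p = 0.032). The same held for the protease Adamts15 (-3.11 ± 0.48, adjusted p = 0.0076), Cdcp1 (-2.90 ± 0.41, adjusted p = 0.0035), the exchange factor Arhgef10 (-2.54 ± 0.56, adjusted p = 0.044) and Gbp11, a guanylate-binding protein (-2.35 ± 0.51, adjusted p = 0.044). Higher were the proteoglycan Cspg5 (4.83 ± 0.60, adjusted p = 0.0018), the hydrolase Abhd1 (3.93 ± 0.85, adjusted p = 0.043), Tiam2 (3.64 ± 0.60, adjusted p = 0.011). So were the magnesium carrier Nipal1 (2.82 ± 0.54, adjusted p = 0.026), the drug pump Abcb1b (2.65 ± 0.36, adjusted p = 0.0029), Arhgef16 (2.62 ± 0.54, adjusted p = 0.036) and the sodium channel Scn8a (2.58 ± 0.33, adjusted p = 0.0023). List members past the threshold included Tgfbr2 (-1.06 ± 0.22, adjusted p = 0.038), the bile acid receptor Nr1h4 (-1.14 ± 0.24, adjusted p = 0.039). Others were the glucose carrier Slc2a1 (1.88 ± 0.41, adjusted p = 0.046), the interferon-induced Rtp4 (-1.11 ± 0.25, adjusted p = 0.048) and Abcd2, a peroxisomal carrier (-2.18 ± 0.46, adjusted p = 0.039).

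Limma called 191 genes between KO and WT (1.2%; 2492 unadjusted), 90 higher and 101 lower. Among these, 56 were also lower in DEN_KO than in DEN_WT (17.6 if independent) and 28 also higher (14.8 if independent), Pla2g4b, Crym, Adamts15 and Abcb1b among them. Camera put 0 lists past the threshold, fry 0, and camera with an estimated correlation 0. The nearest was the interferon list, with 1 of 26 lower (median -0.33; 3 over the list alone, adjusted p = 0.092, and adjusted p = 0.92 with an estimated correlation). The gene count fell to 62 without KO 1, 63 without KO 2 and 65 without WT 2 and rose to 560 without KO 3, and lists past the threshold numbered 5 without WT 3, 1 without KO 2 and 1 without KO 3. Only 7 of 21 named genes kept their call whichever library was left out (Abcb1b, Adamts15, Cdcp1, Crym, Cspg5, Pla2g4b and Scn8a). The other 14 were lost without at least 1 library (highest limma adjusted p = 0.22), 13 of them without KO 1, 13 without KO 2 and 13 without WT 2. Of the 21 calls, 16 were lost with voom weights, 10 with quantile normalization and 7 when only the compared groups were fitted. In simulated data this comparison found 69.7% of 4-fold and 28.4% of 2-fold changes.

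On chromatin of DEN-treated wild type liver, Smyd3 peaks lay at the start sites of Myc (15:61815783-61817603), Ccnd1 (7:152125397-152126024), Egr1 (18:35019243-35021498), Foxm1 (6:128312212-128313478) and Cdk1 (10:68814962-68816065), each with an H3K4me3 region in both genotypes. Smyd3 itself carried a peak (1:181447733-181448729). Gpc3 had a peak (X:49966669-49967511) and an H3K4me3 region in WT but none in KO, as did Cdcp1. Afp, Spp1, Lcn2 and Scd2 had no Smyd3 peak at their start, the nearest lying 12627, 24151, 5425 and 8994 bp away. The Smyd3 list held 27324 peaks (median 775 bp, 23.69 Mb), the H3K4me3 lists 15579 regions in WT (1480 bp, 26.94 Mb) and 17491 in KO (1576 bp, 32.85 Mb). Of the Smyd3 peaks 41.4% (11301; 95% CI 40.8 to 41.9) overlapped H3K4me3 WT regions, against 1.59% (1.39 to 1.73) for random placements, 26.0 times as many, and 43.2% lay within 1000 bp of a start site (3.83% at random). Random placements could fall anywhere on a chromosome, so the excess does not set H3K4me3 apart from start sites in general. KO regions overlapped 86.4% of the WT regions (85.8 to 86.9) and WT regions 76.4% of the KO regions (75.8 to 77.0). Each group has 1 list, so no replicate error can be given, and depth alone can alter how many regions a list holds.

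Smyd3-bound genes numbered 10582 of 16471 tested (64.2%), including 24 of 30 mitosis genes, 22 of 23 cholesterol synthesis genes and all 14 immediate early genes, but 13 of 29 oncofetal markers, 3 of 27 P450 genes and 0 of 26 macrophage markers. In DEN_KO against DEN_WT bound genes had a median of -0.11 and other genes 0.07 (camera p = 0.021, p = 0.0076 with an estimated correlation, p = 0.072 without the library DEN_WT 2 and p = 0.1 without the expression filter, which both end the call). Of 10 splits of the libraries, the real one included, 4 gave a camera p as small, the smallest 0.000529. Bound genes were lower in 19.4% of cases against 13.8% of other genes (Fisher's exact p = 1.8e-20) and higher in 14.3% against 20.3% (Fisher's exact p = 2.3e-23), but genes are not independent replicates and these p-values overstate the evidence. The 11329 genes with H3K4me3 in both genotypes shifted about as much in DEN_KO against DEN_WT (median -0.1, other genes 0.1). Of them 19.7% were lower, against 12.4% of other genes. In DEN_KO against KO, both knockout, bound genes also had the lower median (-0.03, other genes 0.16). In KO against WT and DEN_WT against WT they had the higher (0, other genes -0.07 in each). Whether the DEN_KO against DEN_WT shift is particular to Smyd3 binding was not tested. Without a Smyd3 precipitation from knockout liver, antiserum signal from other proteins cannot be told from binding. Genes with H3K4me3 at the start in WT only numbered 284, Gpc3, Cdcp1, Tspan8 and Akr1c18 among them. Of these 44.0% were raised by DEN (15.7% of other genes) and 34.9% were lower in DEN_KO (17.1% of other genes, median -0.82, camera p = 8.8e-07, and p = 0.0086 with an estimated correlation). Since H3K4me3 marks active start sites, a mark in DEN-treated WT only and more RNA there are not separate findings. Whether Smyd3 acts on these genes was not tested. The 593 genes with H3K4me3 in KO only moved little in DEN_KO against DEN_WT, at a median of 0.11. Of them 21.6% were higher against 16.2% of other genes (camera p = 0.12, and p = 0.59 with an estimated correlation).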

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

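The groups, lists and contrasts of this part were fixed before the data were examined, but every test of an explanation below was chosen only after the result it bears on had been seen. The genes named here were also picked by their values.

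The DEN effect differed between genotypes for 2727 genes by limma, 1438 with a higher and 1289 with a lower effect in KO, and 5271 had an unadjusted p below 0.05. The higher share of 52.7% became 48.7% with the GC correction, so the larger direction rests on that choice. Among genes with a lower DEN effect in KO than in WT were Gpc3 (-5.20 ± 0.52 SE, limma adjusted p = 0.00048), the sodium channel Scn8a (-5.15), Lcn2 (-5.1), the magnesium carrier Nipal1 (-5.00). So were Akr1c18 (-4.90), Gpnmb (-4.78), the secretory cell factor Bhlha15 (-4.41), Igfbp1 (-4.12), the adenylate cyclase Adcy1 (-4.06) and the endotoxin receptor Cd14 (-3.89). Further down came Tiam2 (-3.76), Rhox8 (-3.62), Cspg5 (-3.57), Btg2 (-3.54), D17H6S56E-5 (-3.52), Col4a3 (-3.49), Tspan8 (-3.44). Then came Cyp2a4 (-3.42), Psrc1 (-3.31), Sparc (-3.15), the asparagine synthetase Asns (-3.11), the stress kinase relative Trib3 (-2.98), the lipase relative Pnpla3 (-2.96), Lepr (-2.82), Spp1 (-2.76). Smaller differences were those of Col1a1 (-2.64), Myc (-2.51), Scd2 (-2.44), the pentose phosphate enzyme G6pdx (-2.40), Mdga1 (-2.35), Slc2a1 (-2.20), Sqle (-2.19), Bub1b (-2.02), Ccnd1 (-1.69), Oas1a (-1.64), Ptma (-1.52), Pdcl (-1.29) and the iron carrier Trf (-1.04).

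Higher in the same contrast were Serpina3c (5.99 ± 1.53, limma adjusted p = 0.019), Fitm1 (4.31), the lipid carrier Mfsd2a (4.22), Mir5102 (3.71), the heat shock genes Hspa1b (3.63) and Hspa1a (3.62), Mup11 (3.60), Gsta2 (3.56). So were Mup7 (3.41), Mup18 (3.38), Mup14 (3.38), mmu-mir-2134-2 (3.23), Acot1 (3.12), Plin4 (2.89), Acaa1b (2.63), Cyp2c54 (2.29), Slco1b2 (2.05), Ces1d (1.94), Nr1h4 (1.60), Bst2 (1.40) and Gsta4 (1.34). Smyd3 was not past the threshold (-1.42 ± 0.58, adjusted p = 0.11). Of 41 named genes past the threshold in this contrast and followed library by library, 15 lost their call without at least 1 library (highest adjusted p = 0.11), Igfbp1, Col1a1, Hspa1a and Mup11 among them, most often without KO 1 (13 genes), or without DEN_KO 3, DEN_WT 2 or DEN_WT 3 (11 each). The gene count was 1787 without DEN_KO 3. For some genes of both directions, the difference goes with the level in untreated KO. Cspg5 averaged 6.33 in WT, 180 in KO, 51 in DEN_WT and 131 in DEN_KO. Tiam2 and Slc2a1 were also higher in untreated KO, and Nr1h4 was lower there (3540 in WT, 1586 in KO). In DEN_KO against DEN_WT these genes, in the order named, were not past the threshold (limma adjusted p = 0.12, 0.90, 0.58 and 0.16).

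Camera put 16 of 35 lists past the threshold for this contrast, fry 11, and camera with an estimated correlation 0. Lower in KO by median log2 were the oncofetal list (-2.44, with 12 of 29 members lower, 17 over the list alone, and an adjusted p = 0.43 with an estimated correlation), mitosis (-1.67, 3 of 30 lower, 0 over the list alone, adjusted p = 0.44 with an estimated correlation), p53 targets (-1.05, 9 of 23 lower, adjusted p = 0.43 likewise), cholangiocyte markers (-0.99, 4 of 12, adjusted p = 0.43 likewise), cholesterol synthesis (-0.71, 6 of 23, adjusted p = 0.44 likewise), fibrosis (-0.69, 6 of 25, adjusted p = 0.44 likewise), EMT (-0.66, 3 of 18, adjusted p = 0.43 likewise), DNA replication (-0.50, 5 of 32, adjusted p = 0.62 likewise) and growth signalling (-0.38, 5 of 27, adjusted p = 0.33 likewise). Higher were male-biased genes (1.79, 8 of 17 higher, adjusted p = 0.44 likewise), P450 genes (1.59, 12 of 27, adjusted p = 0.44 likewise), heat shock (1.08, 4 of 11, adjusted p = 0.44 likewise), PPARA targets (1.05, 10 of 26, adjusted p = 0.44 likewise), bile acid genes (0.99, 6 of 21, adjusted p = 0.44 likewise), pericentral genes (0.92, 4 of 17, adjusted p = 0.52 likewise) and NRF2 targets (0.54, 8 of 25, adjusted p = 0.43 likewise). Interferon genes had no common direction past the threshold (median 0.14, camera adjusted p = 0.93), with 1 higher, 2 lower and a fry adjusted p of 0.029 without regard to direction.

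Swapped library labels bear on all counts. With 3 against 3 libraries only 10 splits exist, too few for a share under 0.05. Every split other than the real one divides the groups unevenly and so keeps part of the real difference. The other splits thus do not show what chance alone gives. The real split gave the most genes in DEN_WT against WT (1 of 10 splits as many; 4882, highest other 0), DEN_KO against DEN_WT (1 of 10; 5576, highest other 0), KO against WT (1 of 10; 191, highest other 0) and DEN_KO against KO (1 of 10; 2460, highest other 1). It gave the most lists in DEN_WT against WT (1 of 10; 23, highest other 18) and DEN_KO against KO (1 of 10; 11, highest other 10), but not in DEN_KO against DEN_WT (4 of 10; 16, highest other 18) or KO against WT (10 of 10; 0, highest other 7). Moved-back genes were at 88.1% against 83.4% in the highest other split (1 of 10). For bound genes 4 of 10 splits had a p as small, the real one 0.0207 and the smallest 0.000529. For the difference in DEN effects 3 of 100 splits gave as many genes (2727, highest other 3541). The 9 other splits that kept DEN_WT and DEN_KO whole gave 1591 to 3541 genes and the 90 that mixed them 0 to 2, so that count rests on the DEN-treated livers. For its lists 14 of 100 splits gave as many as the real 16 (highest other 18). Since these splits keep part of the real difference, they neither exclude chance nor point to it.

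The smaller DEN response in knockout livers may reflect a need for Smyd3 in the growth and dedifferentiation of liver cells after DEN, or simply less tumour tissue in the pieces sampled. On the value scale, over members DEN raised in wild type, the DEN_KO rise ran from 7.6% of the DEN_WT rise for fibrosis genes such as Col1a1 (bootstrap interval 0.2 to 29.4) to 47.8% for endothelial markers (24.7 to 94.5), with mitosis at 17.0% (14.6 to 21.5) and interferon genes at 37.6% (26.4 to 53.7). A single common factor for all 14 lists fits poorly with a permutation p = 0.0069, where genes count as independent, though most intervals overlap. Less affected tissue would give such a factor only if every list rose in that tissue alone, which was not tested. The intervals resample the genes of a list as if independent, so the spread between mice enters neither them nor this p. The test therefore cannot weigh against less tumour tissue. Earlier forms of the test set mitosis against the highest list and then against interferon, whose intervals over genes lie apart from it. Counting tumours and sequencing microdissected tumour and neighbouring tissue from both genotypes would separate the 2 readings.

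The 84 genes called the same way with and without DEN, Pla2g4b and Crym among them, could be targets of Smyd3 or marks of strain segments that differ between the mouse lines. Only 2 lie within 20 Mb of Smyd3 (Fisher's exact p = 0.4), which argues against a stretch carried along with the allele. A Smyd3 peak lay at 56.0% of their start sites (exact 95% CI 44.7 to 66.8) and at 64.2% of all tested genes. They were thus not bound more often than other genes. Peaks were read in DEN-treated liver only and at 1 annotated start per gene. A start without a peak therefore does not exclude loss of Smyd3 there. Random sets had as many neighbours within 1 Mb in a share of 0.039 for these genes, 0.048 for the 191 called in KO against WT, and 0.072 and 0.68 for the 191 genes of lowest p in DEN_WT against WT and DEN_KO against KO. Counted as next genes tested the shares were 0.008, 0.0068, 0.0015 and 0.17, and since 1 set of DEN genes clusters and the other does not, strain segments elsewhere stay open (a further form was looked at and is not used). Littermates from a backcrossed line and re-expression of Smyd3 would test this.

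Ribosomal protein genes were higher in DEN_KO than in KO by their median (0.67), with 32 of 74 members higher, 1 lower and a camera p of 0.13 with an estimated correlation. Short transcripts being captured more readily in these libraries could produce it, since other protein-coding genes under 1000 bp were also higher (0.85) against medians of 0.24, -0.01 and -0.11 in the 3 bins of longer genes. Histone genes (1.70, 17 of 32 higher) and ribosomal protein pseudogenes (1.19, 58 of 122 higher) went with them, but small nucleolar RNA genes did not (-0.26, 1 higher and 4 lower). These sets and bins were chosen after the values were seen, with gene span for transcript length, GC content explains little of it (0.53 after its removal), and since all 3 DEN_KO libraries lay above every other library a batch that coincides with the group remains possible. Repeating the libraries in a single randomized batch would tell, and until then the rise of short metabolic genes in DEN_KO may be partly technical.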

How the results depend on the processing

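With the correlation between genes estimated for each list, camera put 0 lists past the threshold in DEN_WT against WT, DEN_KO against DEN_WT, DEN_KO against KO and the interaction, where the preset gave 23, 16, 11 and 16, and all 66 list calls were lost. Tested by fry, DEN_KO against KO kept 6 lists, and 13 list calls were lost in all. Without the expression filter 1 list passed in KO against WT and the bound-gene p was 0.1. KO against WT gave 115 genes when only its own groups were fitted and 121 with voom weights, against 191. Leaving out a library gave 3783 to 4398 genes in DEN_WT against WT and 4020 to 5102 in DEN_KO against DEN_WT. KO against WT gave 62 without KO 1, 63 without KO 2, 65 without WT 2 and 560 without KO 3, and 5 lists without WT 3, 1 without KO 2 and 1 without KO 3. DEN_KO against KO gave 1170 without DEN_KO 2, 1322 without KO 1, 1353 without DEN_KO 3, 1610 without KO 2 and at most 2157. The interaction gave 1787 without DEN_KO 3 and at most 3084. The bound-gene p was 0.072 without DEN_WT 2 and 0.0091 without DEN_WT 3. Moved-back genes stayed between 85.8% and 92.1% under every alternative. A replicate block left every count within 1.5 times (4602, 5288, 2180 and 2463 genes where DEN entered). With each group's mean removed, libraries of different groups with the same number correlated by -0.1 to 0.12. Those with other numbers correlated by -0.152 to 0.132, so no pairing by number was seen, though so few libraries could hide one. Quantile normalization moved the median of all genes to -0.108 in DEN_WT against WT and lost 5 list calls, as did the stricter filter. Single-gene calls were lost in 36 cases with quantile normalization, 42 with the GC correction, 51 with it and a block, 41 without the filter, 47 with voom weights, 28 with fits of the compared groups, 22 with the block, 9 with trimmed mean scaling, 6 with a pseudocount of 8 and 2 with 0.5, and none reversed. Of the 42 lost with the GC correction, 32 fell in DEN_KO against KO. H3K4me3 WT regions overlapped by KO regions were 83.7% at 50% overlap and 83.9% in the longer regions. Smyd3 peaks in H3K4me3 regions were 40% at 50% overlap and 42.3% with widened regions. Factors of the median-ratio kind were not run, because the values carry them, nor another count test, nor splits by peak score.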

Other observations

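Lists not described so far moved little as groups with DEN in wild type, though single members did. Hepatocyte identity genes had 3 of 26 higher, 5 lower and 18 not past (camera adjusted p = 0.49), with Trf, the iron carrier of serum, higher by 2.63 ± 0.21 SE (limma adjusted p = 3.2e-06). Lipogenesis had 5 of 18 higher and 4 lower (adjusted p = 0.51), with Pnpla3, a lipid droplet lipase relative, from 22 ± 16.1 to 1164 ± 463 (n = 3; 5.81 ± 0.56, adjusted p = 1.1e-05). ER stress genes had 2 of 21 higher and 1 lower (adjusted p = 0.79), the higher ones including Asns, asparagine synthetase (4.67 ± 0.65, adjusted p = 0.00018), and Trib3, a stress-induced pseudokinase (3.30 ± 0.35, adjusted p = 2.4e-05). NRF2 targets split into 4 of 25 higher and 10 lower (adjusted p = 0.68), with G6pdx higher by 3.24 ± 0.33 (adjusted p = 1.8e-05) and Gsta2 lower (-2.96 ± 0.34, adjusted p = 4.3e-05). Glycolysis had 7 of 16 higher (adjusted p = 0.086), Slc2a1 among them (1.82 ± 0.41, adjusted p = 0.0049). Periportal genes had 4 of 16 higher and 6 lower (adjusted p = 0.43).

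Markers of lymphocytes, neutrophils and tissues outside the liver changed in few genes. T and NK cell markers had 1 of 15 higher (camera adjusted p = 0.49), B and plasma cell markers 2 of 11 (adjusted p = 0.24) and neutrophil markers 1 of 7 with 1 lower (adjusted p = 0.55). Erythroid genes had 1 of 5 lower (adjusted p = 0.54), exocrine pancreas genes 1 of 4 higher and 1 lower (adjusted p = 0.94) and adipocyte genes 2 of 7 higher and 1 lower (adjusted p = 0.79). Circadian genes had 2 of 20 higher and 6 lower (fry adjusted p = 0.013 without regard to direction), SMYD and H3K4 methylation genes 2 of 20 higher (0.036 likewise) and sex-linked genes 1 of 5 lower (0.21 likewise). Mitochondrially encoded genes are absent from the table and were not analysed here.

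All 12 livers read as male. Xist, the X inactivation RNA, ran from 4 to 29, against 697 to 1575 for Ddx3y, 168 to 452 for Kdm5d, 141 to 346 for Uty and 565 to 1890 for Eif2s3y. In DEN_KO against DEN_WT Kdm5d was lower (-0.88 ± 0.18, limma adjusted p = 0.0027), as was Uty (-0.69 ± 0.20, adjusted p = 0.017). Untreated livers went the same way for Kdm5d, at 452, 432 and 347 in WT and 219, 231 and 270 in KO. That difference was not past the threshold.

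Respiratory chain genes fell with DEN in wild type (median -0.83, 0 of 82 higher and 58 lower) and were higher in DEN_KO than in DEN_WT (median 1.09). Their DEN effects differed between genotypes (median 1.29, 60 higher and 0 lower; camera p = 0.0044 with an estimated correlation). Other protein-coding genes under 1000 bp had nearly the same medians, 1.04 in DEN_KO against DEN_WT and 1.22 between the DEN effects, though fewer of their members passed, 136 of 280 against 64 of 82 in DEN_KO against DEN_WT and 91 of 280 against 60 of 82 between the DEN effects. In DEN_KO against KO the medians were 0.50 for the respiratory chain and 0.85 for the short genes. How much of the respiratory chain's rise goes with short genes in general was not tested. With DEN in wild type those short genes had a median of -0.28. Both sets were put together after the values were seen.

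H3K4me3 regions found in 1 genotype only were short, with medians of 437 bp for the 2123 of WT and 583 bp for the 4127 of KO against 1619 bp for shared ones. Smyd3 peaks lay on 23.4% and 18.0% of them, against 73.7% of shared regions. Genes raised by DEN and lower in DEN_KO were bound in 69.2% of cases, those lowered and then higher in 57.3%, and those called in neither comparison in 64.5%.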
